A study of Mus musculus with 4 samples.

How the data were processed

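The study profiled poly(A) RNA of leukaemia stem cells, the fraction of leukaemic bone marrow cells that can restart the disease, isolated from C57BL/6 mice. Cells came from wild-type mice (WT) and from mice carrying a knockout of Rreb1, a zinc-finger protein that binds RAS-responsive DNA elements (KO), with 2 biological replicates per genotype per the labels. The labels do not say whether a replicate was 1 mouse or a pool, nor which part of the gene was removed. Per the labels' protocols, mRNA was selected on oligo-dT beads, fragmented, and copied from random primers with a kit whose description does not mention marking of the strand. Reads of a gene and of an overlapping gene on the other strand are therefore treated here as not separable. Some labels disagree: the second KO library carries a genotype label naming Rreb2, and the extraction text speaks of tumour-associated macrophages while the titles name leukaemia stem cells. Libraries were grouped by their titles.

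Per the submitters' processing notes, CASAVA, HISAT2 2.1.0, featureCounts and DESeq2 were used with the GRCm38 genome build. Their roles and order are not given in the sources used here. The authors deposited 1 table of 16442 genes by 4 libraries. Its unit is not named, and was inferred from the values: the deposited numbers behaved as FPKM (fragments per kilobase of exon, scaled to the assigned fragments of the library) with 1 added to every value, since the lowest value was exactly 1. That 1 was subtracted. Genes were matched by symbol to GENCODE M21 (GRCm38), where 16014 of the 16442 (97.4%) matched 1 annotated gene. FPKM multiplied by the exonic length fell on whole multiples of 1 step per library, within a tolerance of 0.05, for 99.0% to 99.2% of values of up to 30 reads. Whole reads could be recovered in all 4 libraries for 15787 genes, 98.6% of those matched. The steps gave depths of 18451251 and 16590830 assigned reads in the WT libraries and 18420466 and 17037493 in the KO libraries. At those depths 3 reads on a gene with 2 kb of exons amount to 0.0813 to 0.0904 FPKM, which covers counting error only. The table holds a subset of annotated genes, chosen by a rule not given in the sources used here, and 236 genes were at 0 in every library. Genes outside it were not analysed here.

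Because the values were FPKM and not counts, the branch of the plan for normalized values was used. Differences between KO and WT were tested with limma 3.58.1 (R 4.3.3), in its trend form, on log2(FPKM + 1), for the 11768 genes with a mean of at least 1 FPKM. The design had group as the only term, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom and 4.10 prior degrees of freedom. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low level. A permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so all p-values rest on the spread that limma shares between genes.

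Before the data were examined, 45 gene lists were fixed from textbook knowledge. They cover respiratory complexes and other metabolism, translation, proliferation, stress, signalling, leukaemia self-renewal, myeloid differentiation, other marrow cell types and RNA handling. All 45 had at least 3 tested members. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 45 lists, with camera at an estimated correlation and limma's fry beside it. Genes named in the text were set by a rule fixed at the same time: Rreb1, the 12 largest rises and the 12 largest falls among called genes with both KO libraries on 1 side of both WT libraries, up to 4 members per list by smallest p, and 8 genes named whatever their p (Sdha, Sdhb, Sdhc, Sdhd, Eef1a1, Hoxa9, Meis1 and Myc). Gene models without a symbol were only counted. Other genes that are named were chosen after their values were seen, and this is said where they appear.

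The procedure was tested on simulated reads for the 11373 tested genes with recovered reads. It recovered 32.8% of genes changed by a fold of 1.5, 80.6% at a fold of 2 and 86.4% at a fold of 4, and called 9 unchanged genes. Of simulated lists of 20 genes, 10 of 10 with a shift of 0.5 on the log2 scale were called with the preset correlation, 9 of 10 with the estimated one, and 0 of 30 without a shift with either. The simulated genes varied independently, with 1 overdispersion (0.0047) for all. In the data, estimated correlations of the called lists ran from −0.078 (complex II) to 0.46 (fatty acid oxidation). The simulation therefore does not give the rate of false calls for lists whose genes move together. To see whether 1 library was deposited 2 times, replicates were compared by a chi-square per gene on recovered reads. It was 11.6 for the WT pair and 13.8 for the KO pair, so neither pair agreed within sampling noise, and it is used for nothing else. Alternatives were another pseudocount, no filter, each library left out, the replicate number as a block, limma-voom on recovered reads, a fold threshold and, added after the data were seen, 2 other scalings of the libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.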

Results

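Leukaemia stem cells from the bone marrow of WT and Rreb1-KO mice were compared by mRNA sequencing, with 2 libraries per genotype. The series concerns translation of nuclear-encoded mitochondrial respiratory proteins and succinate metabolism in acute myeloid leukaemia, so the mRNA data address whether transcript levels of those proteins, or of other programmes, differ without Rreb1. Depth was 16590830 to 18451251 assigned reads per library. The granulocyte precursor gene Elane, neutrophil elastase, was at a high level, 6162 ± 1355 FPKM in WT and 6735 ± 665 in KO (SD, n = 2). Levels of such genes varied, with Mpo at 354 ± 63.3 and 179 ± 18.5 FPKM and Gfi1 at 6.68 ± 1.08 and 11.1 ± 3.29. The leukaemia transcription factor genes Hoxa9 and Meis1 were at 29.6 ± 1.01 and 11.1 ± 0.472 FPKM in WT. Elane was chosen after its values were seen.

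The targeted gene was examined first. Rreb1 (chromosome 13, 37778400 to 37952005, plus strand, GRCm38) stood at 5.24 and 6.57 FPKM in the WT libraries and at 6.10 and 6.93 FPKM in the KO libraries, from 1353 and 1525 against 1572 and 1652 reads. Its log2 fold change was 0.13 (95% limits −0.20 to 0.45, limma adjusted p = 0.616), and the groups overlapped. Without WT replicate 1 it was −0.013. The value covers all exons of the gene, so it would not show the loss of a short part of it, and the transcript data leave the genotype labels unchecked. All directions that follow are therefore between the libraries labelled KO and the libraries labelled WT, and KO and WT stand for those labels.

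Between these libraries, 71 genes rose and 48 fell in KO (limma, adjusted p below 0.05, 11768 genes tested), and 2440 genes had an unadjusted p below 0.05. The genes that rose were led by the globins, genes of neutrophil granules, the stefin and cystatin cluster, Olfm4, Ly6a2 and Cyp26a1. Those that fell were led by the basophil protease Prss34, Selenop, the macrophage genes C1qc and Lgmn, the proton-pump subunit Atp6v0d2, and immunoglobulin genes. The other ways of dividing the 4 libraries into pairs called 0 and 0 genes by limma (169 and 212 at an unadjusted p below 0.05) and 0 and 0 by limma-voom. Groups did not overlap in 55.3% of tested genes, against 33.3% by chance, and the first principal component (58.4% of variance) placed the WT libraries at −19.5 and −13.5 and the KO libraries at 9.29 and 23.7. With 1 library left out fewer genes were called in either direction. Those fits had fewer samples and 1 group of a single library. Lost power therefore cannot be told apart from the influence of the library left out. This holds for all counts of called genes given below with 1 library left out. The counts depended on the filter and test, with 22 and 10 without the filter on level and 501 and 340 by limma-voom on recovered reads.

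**Figure D1:**
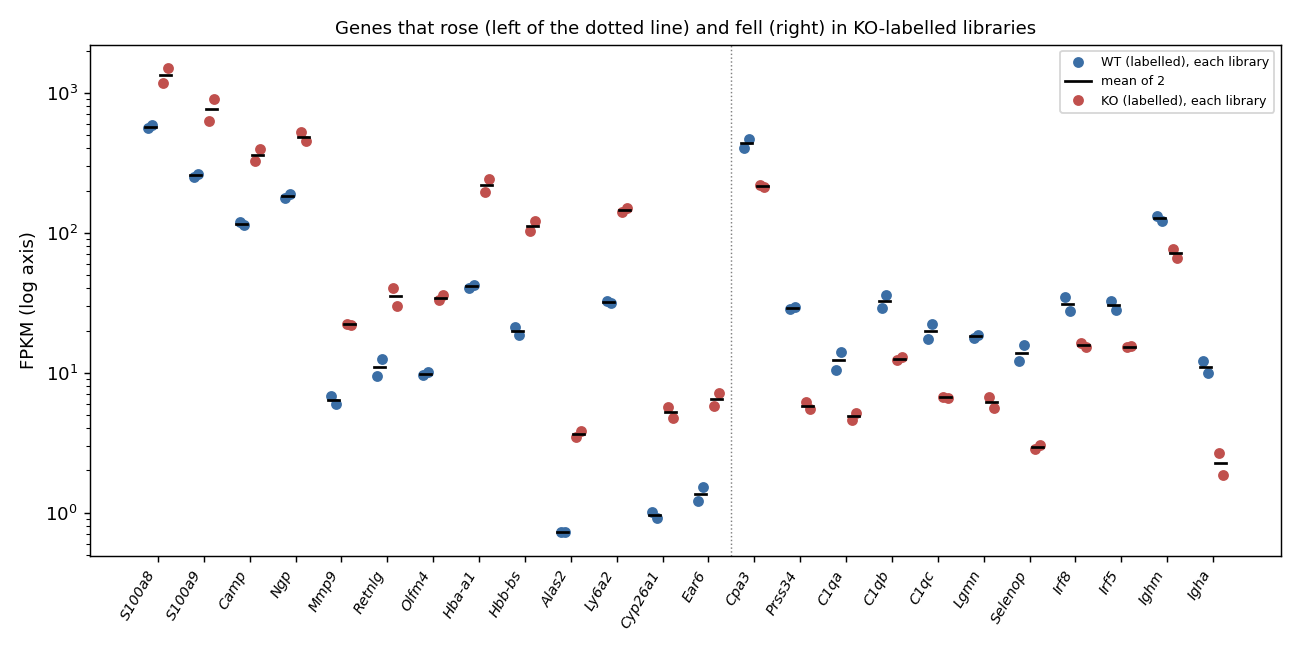
FPKM per library (log axis) of genes that rose (left of the dotted line) and fell (right) in the KO-labelled libraries, chosen from the genes called and drawn with 1 point per library and a bar at the mean of 2. For each gene both KO points lie on the same side of both WT points, for example 572 in WT against 1340 in KO as mean FPKM of S100a8.

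The mature neutrophil list showed the clearest rise. Of its 22 tested genes 10 rose, 0 fell and 12 did not pass the test, with a median log2 fold change of 0.81 (camera adjusted p = 1.58e-09; adjusted p = 0.727 with an estimated correlation). The matrix metalloprotease Mmp9, released from neutrophil granules, went from 6.40 ± 0.648 to 22.2 ± 0.197 FPKM (SD, n = 2 in each group), a log2 change of 1.65 (SE 0.099, adjusted p = 0.0042). The antimicrobial peptide gene Camp rose by 1.62 (SE 0.12, adjusted p = 0.0091) and the granule protein gene Ngp by 1.39 (SE 0.11, adjusted p = 0.0115). The cysteine protease inhibitor Stfa1 went from 159 ± 3.88 to 467 ± 76.8 FPKM, and S100a8, 1 chain of calprotectin, from a mean of 572 to 1340 FPKM. The others that rose were S100a9, Lcn2, Padi4, Retnlg and Stfa2. Ltf, a further granule gene of the list, was at 22.9 ± 0.828 and 22.9 ± 9.25 FPKM (log2 change −0.05, adjusted p = 0.915), and the chemokine receptor gene Cxcr2 was at 2.18 and 1.95. S100a8 and the list members named after it were chosen after their values were seen. In total 14 rose when adjusted over the list alone. The 10 rises became 1 without WT replicate 1, 1 without WT replicate 2, 4 without KO replicate 2 and 5 without the filter on level. Stfa1, Stfa2 and the related genes Cstdc4 and Cstdc5, which rose by 1.73 and 1.76, are near-identical copies whose reads cannot be assigned with certainty.

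Genes of the primary granules, made earlier in granulocyte development, were not called as a list (16 tested, 0 changed, median 0.04, camera adjusted p = 0.786, test direction lower). Adjusted over the list alone 1 fell and 0 rose, and limma-voom called 1 rise and 2 falls. Myeloperoxidase (Mpo) was at 354 ± 63.3 FPKM in WT and 179 ± 18.5 in KO, a log2 change of −0.97 with an adjusted p = 0.053. The regulator Cebpe was at 184 ± 10.3 and 233 ± 17.1 FPKM (log2 change 0.33, adjusted p = 0.166).

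Macrophage genes were lower as a list. Of 15 tested, 4 fell, 0 rose and 11 did not pass, with a median of −0.79 (camera adjusted p = 4.50e-07; adjusted p = 0.727 with an estimated correlation). The 3 chains of complement C1q, C1qa, C1qb and C1qc, fell by 1.16, 1.30 and 1.43 on the log2 scale (SE 0.15, 0.12 and 0.13, adjusted p = 0.034, 0.015 and 0.013). The lysosomal protease Lgmn went from 18.2 ± 0.601 to 6.15 ± 0.760 FPKM (adjusted p = 0.0091). In total 10 fell when adjusted over the list alone. Apoe, an abundant member chosen after its values were seen, was at 214 ± 16.0 and 209 ± 3.65 FPKM (adjusted p = 0.896). Selenop, a secreted selenium carrier that is not in the macrophage list, fell by 1.90 (SE 0.14, adjusted p = 0.0091). In the monocyte list (17 tested, median −0.20, camera adjusted p = 0.0045; adjusted p = 0.727 with an estimated correlation) 3 fell and 0 rose. These were Irf8 and Irf5, transcription factors of the monocyte lineage and of innate signalling, each near 31 FPKM in WT and 15 to 16 in KO (log2 changes −0.92 and −0.94, adjusted p = 0.039 and 0.020), and Ms4a6c (−0.65, adjusted p = 0.0497). Adjusted over the list alone, 6 fell and 1 rose. The 4 macrophage calls became 0 without WT replicate 1 or 2, 1 without KO replicate 1 or 2 and 2 without the filter on level (median −0.40). The monocyte median ran from −0.12 without WT replicate 1 to −0.37 without KO replicate 2, and the 3 monocyte falls became 0 with each library left out in turn, and without the filter, while 1 member rose without KO replicate 1.

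The B cell list and the T and NK cell list were called lower in KO by camera. In the B cell list 3 of 8 tested genes fell and 0 rose (median −0.33, camera adjusted p = 0.0108; adjusted p = 0.727 with an estimated correlation). Ighm, the heavy chain of immunoglobulin M, went from 127 ± 8.44 to 71.1 ± 7.31 FPKM, Igkc from 54.7 ± 2.74 to 29.0 ± 2.75 and Jchain from 3.69 ± 0.437 to 1.02 ± 0.260 (adjusted p = 0.034, 0.023 and 0.038). Adjusted over the list alone, 4 fell and 1 rose, and with the replicate number as a block 1 fell and 0 rose. Igha, the heavy chain of immunoglobulin A, fell by 1.89 (SE 0.16, adjusted p = 0.0125). Immunoglobulin genes together took 0.0364% ± 0.00139 of assigned reads in WT and 0.0208% ± 0.00191 in KO (SD, n = 2). Among variable segments, Igkv8-19, Ighv7-3, Igkv9-120 and Ighv6-3 fell, and Igkv4-90 had 10 and 16 reads in WT and 0 and 0 in KO. These segments resemble each other and share reads. In the T and NK cell list (12 tested, 0 changed, median −0.43, camera adjusted p = 0.0137; adjusted p = 0.727 with an estimated correlation) members lay on either side. Trbc1 was at 3.49 ± 0.276 and 1.51 ± 0.297 FPKM and Gzma at 6.81 ± 1.47 and 2.41 ± 1.04 (adjusted p = 0.070 and 0.087), while Tbx21 was at 1.20 ± 0.153 and 2.56 ± 0.0190 and Thy1 at 2.99 ± 0.193 and 5.93 ± 1.57 (adjusted p = 0.095 and 0.108). Adjusted over the list alone, 6 fell and 2 rose. Its camera adjusted p was 0.059 without WT replicate 2, and the 3 B cell calls became 0 without WT replicate 1, WT replicate 2, KO replicate 2 or the filter on level and 1 without KO replicate 1.

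Haemoglobin transcripts were several times higher in KO. Hba-a1 (chromosome 11, 32283511 to 32284465) went from 41.5 ± 1.28 to 219 ± 31.2 FPKM, a log2 change of 2.36 (SE 0.12, adjusted p = 0.0018). Hba-a2 rose by 2.52, Hbb-bs by 2.43 and Hbb-bt by 2.12 (adjusted p = 0.0018, 0.0018 and 0.024), and Alas2, the erythroid enzyme of haem synthesis, by 1.42 (adjusted p = 0.018). Each pair of globin genes is near-identical, so the split within a pair is uncertain. Globins took 0.00651% ± 0.000351 of assigned reads in WT and 0.0353% ± 0.00497 in KO. In the erythroid list 5 of 12 tested genes rose, 0 fell and 7 did not pass (median 0.37, camera adjusted p = 0.039; adjusted p = 0.815 with an estimated correlation). Adjusted over the list alone, 7 rose and 5 fell. With the replicate number as a block the list was not called (camera adjusted p = 0.070) and 4 members rose. The list was not called without WT replicate 2 (adjusted p = 0.345), without the filter on level (0.627, median −0.19) and with a pseudocount of 0.1 (0.050), and its 5 rises became 2 without WT replicate 1 and 3 without WT replicate 2 or KO replicate 2.

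The list of mast cell, basophil and eosinophil genes went both ways and was not called (10 tested, 2 rose, 2 fell, camera adjusted p = 0.786, median 0.06 and test direction lower). Adjusted over the list alone, 5 rose and 4 fell, and limma-voom called 4 rises and 4 falls. Without the filter on level the median was −0.18. With 1 library left out its median ran from −0.093 (without WT replicate 1) to 0.24 (without WT replicate 2), the 2 rises became 1 without KO replicate 1 and 0 without each of the others, and the 2 falls became 1 in all 4 cases. Prss34 (chromosome 17, 25298394 to 25300165), a serine protease of basophils, went from 28.9 ± 0.452 to 5.81 ± 0.464 FPKM (log2 change −2.14, SE 0.092, adjusted p = 0.0018). The mast cell carboxypeptidase Cpa3 went from 435 ± 47.8 to 217 ± 5.90 FPKM (adjusted p = 0.024). Ear6, an eosinophil ribonuclease with close paralogs, and Siglecf, an eosinophil surface lectin, rose by 1.66 and 0.71 (adjusted p = 0.013 and 0.047). Megakaryocyte genes (5 tested) and stromal and endothelial genes (5 tested) had 0 called members and camera adjusted p = 0.819 and 0.959. Of the stromal and endothelial genes 4 had an unadjusted limma p below 0.05, 2 in each direction. Adjusted over that list alone, 1 rose and 2 fell, and limma-voom called 1 rise and 1 fall. The dendritic cell and MHC class II list was lower (11 tested, 0 changed, median −0.13, camera adjusted p = 0.035; adjusted p = 0.727 with an estimated correlation), and this call ended without WT replicate 1 (adjusted p = 0.158), without KO replicate 2 (0.104) and without the filter on level (0.073).

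Other genes among the largest changes had varied functions. Olfm4, a glycoprotein of neutrophil granules and gut stem cells, went from 9.80 ± 0.327 to 34.4 ± 2.03 FPKM (log2 change 1.71, SE 0.088, adjusted p = 0.0020). Cyp26a1, which degrades retinoic acid, went from 0.962 ± 0.0703 to 5.22 ± 0.678 FPKM (adjusted p = 0.012), and Ly6a2, of the Ly6 family of surface proteins, from 32.0 ± 0.684 to 145 ± 7.77 FPKM (adjusted p = 0.0018). Atp6v0d2 went from 4.13 ± 1.32 to 0.305 ± 0.218 FPKM (adjusted p = 0.028). The microRNA loci Mir6362, Mir7224, Mir7048 and Mir6374 were called on few reads. Mir6362 had 0 and 0 reads in WT against 5 and 8 in KO, Mir7224 had 0 and 0 against 3 and 3, Mir7048 had 3 and 3 against 0 and 0, and Mir6374 had 6 and 6 against 1 and 1. The last 3 were not called by limma-voom on recovered reads (adjusted p = 0.109, 0.105 and 0.129). Gene models without a symbol made up 18 of the rises and 2 of the falls.

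Genes of succinate dehydrogenase (respiratory complex II), the enzyme that oxidises succinate, were called lower in KO as a list and not singly. Sdhd was at 161 ± 1.45 and 131 ± 10.5 FPKM (log2 change −0.29, SE 0.094, adjusted p = 0.180) and Sdha at 75.3 ± 5.04 and 61.3 ± 4.14 (−0.29, SE 0.094, adjusted p = 0.181). Sdhb and Sdhc had log2 changes of −0.26 and −0.20 (adjusted p = 0.312 and 0.269), and the assembly factor Sdhaf4 −0.40 (adjusted p = 0.105). Both KO libraries lay below both WT libraries for all 5 of these genes, none of which was called. That separation was found for 2925 of the 11768 tested genes, and Sdhaf4 was named for having the smallest p of the list. As a list, complex II was lower (8 tested, 7 below zero, 0 changed, median −0.23, camera adjusted p = 0.0137; adjusted p = 0.727 with an estimated correlation), and adjusted over the list alone 1 fell. By limma 3 members had an unadjusted p below 0.05, all of them lower, and limma-voom called 0.

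**Figure D2:**
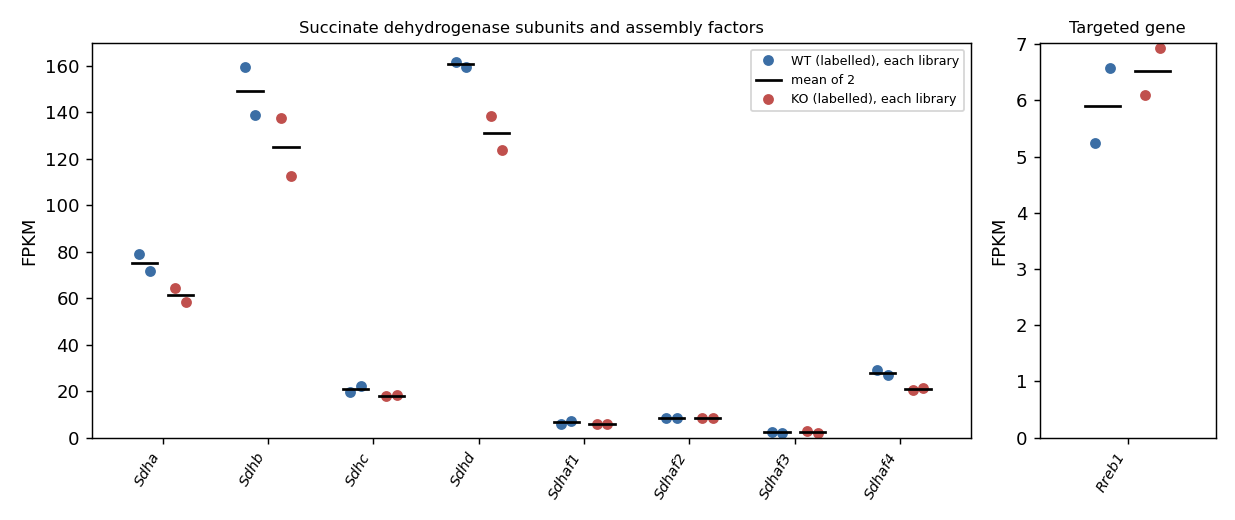
FPKM per library (axes from 0) of the 8 complex II subunits and assembly factors and, on its own axis, of the targeted gene Rreb1, with 1 point per library and a bar at the mean of 2. Sdhd lies at 162 and 160 FPKM in the WT-labelled libraries and at 138 and 124 in the KO-labelled ones, while the Rreb1 points of the groups overlap.

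The TCA cycle list was lower too (19 tested, 16 below zero, 0 changed, median −0.17, camera adjusted p = 0.0023; adjusted p = 0.727 with an estimated correlation), with Idh2 at 60.5 ± 0.00652 and 49.9 ± 0.867 FPKM and Dlat at 22.1 ± 0.229 and 18.6 ± 0.320. In it 5 members had an unadjusted p below 0.05, all lower, and limma-voom called 0. Mitochondrial ribosomal proteins (76 tested, 0 changed, median −0.07, adjusted p = 0.0045; 0.815 with an estimated correlation) and fatty acid oxidation (17 tested, 0 changed, median −0.18, adjusted p = 0.0075; 0.815 with an estimated correlation) were also called lower by camera, and both calls ended without KO replicate 2 (adjusted p = 0.104 and 0.194). Unadjusted p were below 0.05 for 11 and 3 of their members, all lower, and limma-voom called 7 and 0 of them lower. The other respiratory lists were not called: complex I (36 tested, median 0.06, camera adjusted p = 0.786), complex III (9 tested, median 0.09, adjusted p = 0.793, test direction lower), complex IV (12 tested, median −0.05, adjusted p = 0.786) and ATP synthase (18 tested, median 0.01, adjusted p = 0.786, test direction lower). In each of them 0 genes changed by limma, with 11, 2, 4 and 3 members at an unadjusted p below 0.05, while limma-voom called 1 rise in complex I and 2 falls in ATP synthase. Among their members, Ndufb7 of complex I was at 0.40 (adjusted p = 0.116), and ATP synthase genes went both ways, with Atp5a1 at −0.39 and Atp5e at 0.31 (adjusted p = 0.126 and 0.198). mRNAs of the mitochondrial genome (12 tested, 0 changed, median 0.27, adjusted p = 0.317) took 0.911% and 1.32% of reads in WT and 0.969% and 1.72% in KO. One of them, mt-Atp8, was at 193 FPKM in WT replicate 1 and at 2.7 to 7.2 in the other libraries. Mitochondrial protein import (27 tested, median −0.10, adjusted p = 0.069) and mitochondrial biogenesis (15 tested, 0.786) were not called and had 0 genes changed by limma. The same held for glycolysis (22 tested, 0.924), hypoxia targets (17 tested, 0.154) and antioxidant genes (18 tested, 0.111). It also held for sterol synthesis (21 tested, 0.759) and haem and iron metabolism (23 tested, 0.428). By limma-voom 2 protein import genes fell, 1 glycolysis gene rose and 1 fell, and 1 hypoxia target rose. There were 1 rise and 4 falls in antioxidant genes by limma-voom, and 2 rises and 1 fall in haem and iron genes. Adjusted over the list alone, 1 protein import gene fell, and 1 antioxidant gene rose and 1 fell.

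**Figure D3:**
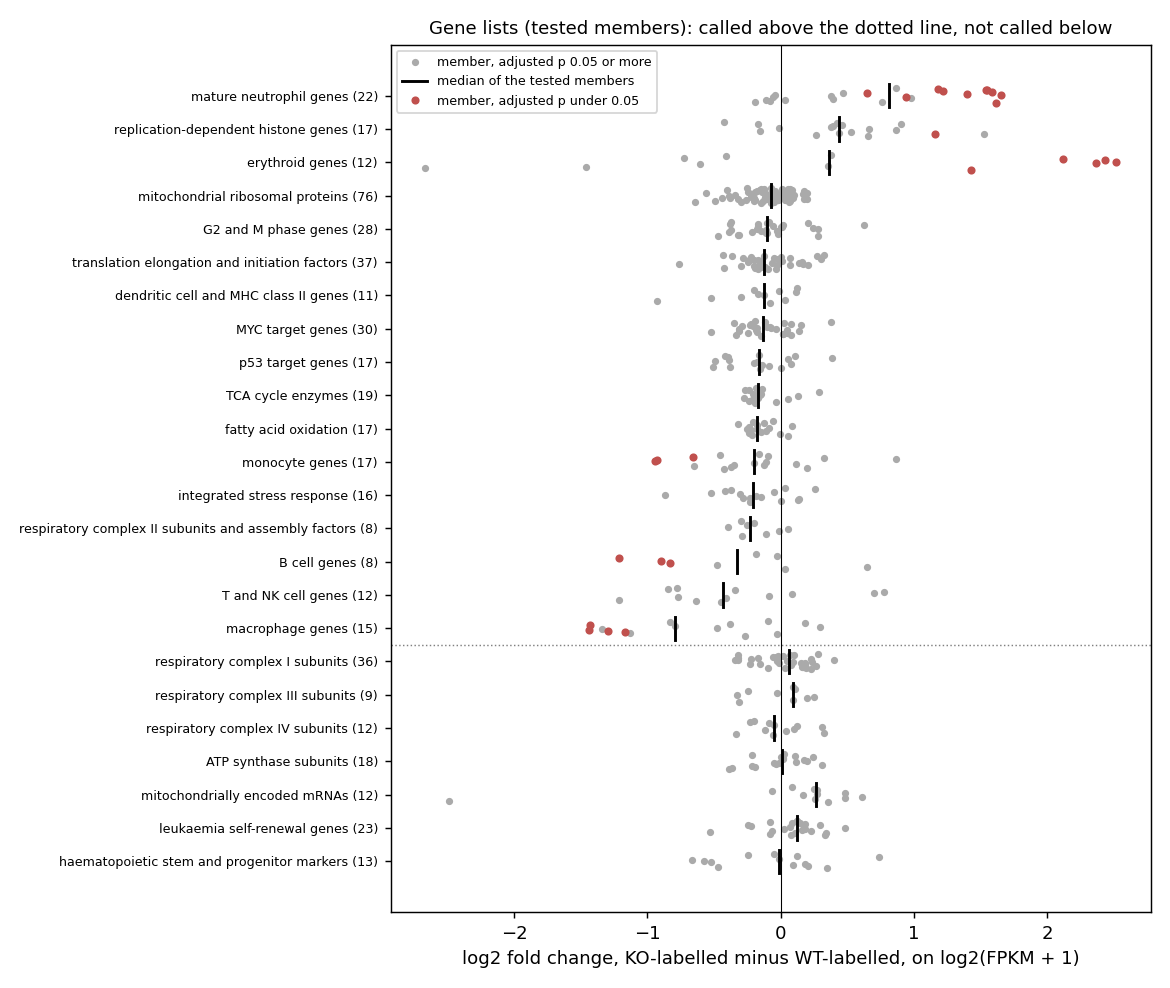
Log2 fold change (KO-labelled minus WT-labelled, on log2(FPKM + 1)) of every tested member of the 17 lists called by camera (above the dotted line) and of 7 lists not called (below it), with red points for genes with an adjusted p below 0.05 and a black bar at the median. Medians run from −0.79 for macrophage genes to 0.81 for mature neutrophil genes, and the metabolic lists lie close to 0 with 0 called members.

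Lists of translation and growth were lower with small medians and 0 genes changed by limma each. limma-voom called 2 falls in translation factors, 1 in MYC targets and 3 in the integrated stress response, with 0 rises. It called 1 rise and 2 falls in p53 targets, and 1 rise and 4 falls in G2 and M phase genes. Adjusted over the list alone, 4 genes of the integrated stress response fell. Translation factors (37 tested) had a median of −0.12 and a camera adjusted p = 0.0147 (0.727 with an estimated correlation), and MYC targets (30 tested) −0.13 and 0.0075 (0.727). The integrated stress response (16 tested) had −0.21 and 0.0075 (0.727), with the serine synthesis genes Phgdh and Psat1 at −0.87 and −0.52 (adjusted p = 0.090 and 0.066). p53 targets (17 tested) had −0.16 and 0.0137 (0.727), and G2 and M phase genes (28 tested) −0.10 and 0.024 (0.908). The calls of translation factors, p53 targets and G2 and M phase genes ended without WT replicate 2 (adjusted p = 0.069, 0.069 and 0.495), and that of G2 and M phase genes also without KO replicate 2 (0.125). Eef1a1, the elongation factor that brings aminoacyl-tRNA to the ribosome, was at 655 ± 65.7 and 638 ± 31.7 FPKM (log2 change −0.04, adjusted p = 0.890; log2 change 0.067 without WT replicate 2 and log2 change 0.015 without KO replicate 1). Cytosolic ribosomal proteins (80 tested, median 0.10, adjusted p = 0.087) and S phase genes (28 tested, median 0.07, adjusted p = 0.089) were not called.

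Leukaemia self-renewal genes were not called and none of 23 tested changed (median 0.13, camera adjusted p = 0.375; 6 members at an unadjusted p below 0.05, and 1 rise and 1 fall by limma-voom). Hoxa9, Meis1 and Myc had log2 changes of 0.18, 0.07 and −0.25 (adjusted p = 0.314, 0.693 and 0.257). Stem and progenitor markers (13 tested, 0 changed, median −0.01, camera adjusted p = 0.687) held members on either side: the receptor gene Kit was at 3.95 ± 0.423 and 7.26 ± 0.146 FPKM (adjusted p = 0.051), while Cd34 was at 69.9 ± 2.25 and 50.2 ± 0.467 and Flt3 at 27.2 ± 1.41 and 18.6 ± 1.29 (adjusted p = 0.065 and 0.069). Adjusted over the list alone, 2 rose and 4 fell. The signalling lists had 0 changed genes and were not called: NF-kB and inflammatory genes (13 tested, adjusted p = 0.102), interferon response (26 tested, 0.640), RAS and MAPK output (4 tested, 0.786), TGF-beta and SMAD targets (9 tested, 0.786), immediate early genes (14 tested, 0.274) and the BCL-2 family (17 tested, 0.786). In NF-kB genes and in the BCL-2 family limma-voom called 0 rises and 2 falls each. It called 2 rises and 1 fall in interferon genes, and 1 rise and 0 falls in TGF-beta targets. Adjusted over the list alone, 2 NF-kB genes fell, 1 BCL-2 family gene rose and 1 fell, and 1 TGF-beta target rose. Sex-linked genes (4 tested, adjusted p = 0.786) did not separate the groups as a list, with Uty at 3.37 ± 0.360 and 3.37 ± 0.274 FPKM.

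Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were higher as a list (17 tested, 1 rose, 0 fell, median 0.44, camera adjusted p = 0.0023; adjusted p = 0.756 with an estimated correlation). H1f5, a linker histone, went from 54.3 ± 0.821 to 125 ± 32.9 FPKM (adjusted p = 0.0497), and adjusted over the list alone 6 rose. The list's median was 0.23 without KO replicate 2 and 0.78 without KO replicate 1. Among all calls, 4 small nuclear and 4 small nucleolar RNA genes rose and 0 of either fell. Mitochondrial ribosomal RNA took 0.346% and 0.481% of reads in WT and 0.534% and 0.879% in KO. Nuclear long non-coding RNAs (12 tested, median 0.25, adjusted p = 0.154) were not called.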

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

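The alternatives were chosen before the data were examined, except both rescalings of the FPKM. All 119 called genes had both KO libraries on 1 side of both WT libraries. Their direction therefore could not turn with another pseudocount, no filter, the block or a library left out. It was also kept under both rescalings, whose factors ran from 0.981 to 1.01, and for the 112 genes tested by limma-voom. The number called again was 104 with a pseudocount of 0.1, 91 and 90 after scaling by the median of ratios and by the upper quartile, 96 by limma-voom, 57 with the block and 31 without the filter on level. It was 6, 8, 35 and 15 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2. The lone library left in a group is then assumed to vary like the other group.

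Genes higher in KO numbered 22 and genes lower 10 without the filter, where 16206 genes were tested. By limma-voom on recovered reads they numbered 501 and 340, for which the cause was not tested, and members called in the 38 lists with 0 limma calls numbered 23 and 45. A fold of at least 2 left 40 and 22 by construction. Leaving out 1 library gave 4 to 50 higher and 2 to 14 lower, with fewer samples in the fit. With the replicate number as a block the counts were 40 and 26, with 5 lists higher, the erythroid list not called (adjusted p = 0.070) and no other list call lost. Whether the numbers mark a shared preparation is not known here. The differences between replicates of the groups correlated at 0.0090 across genes, so no shift shared by number was seen. The Rreb1 log2 fold change was −0.013 to 0.27 with 1 library left out, and below 0 only without WT replicate 1, where the cause was not tested. Eef1a1 ran from −0.14 without WT replicate 1 to 0.067 without WT replicate 2, with 0.015 without KO replicate 1.

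Lists higher in KO numbered 4 to 6 and lists lower 11 to 15 with 1 library left out. With all 4 libraries 3 lists were called higher and 14 lower. Leaving out a library thus added calls among lists given above as not called, and these are not named here. With an estimated correlation and by fry, 0 lists were called in either direction. The lowest adjusted p were 0.727 and 0.206, and 0 lists had an unadjusted p below 0.05 with the estimated correlation, while fry's test of change in either direction called 22. The median of all genes moved by at most 0.02 on the log2 scale under either scaling. Of the alternatives planned for deposited counts, limma-voom alone was run, on recovered reads. TMM, size factors, filters on counts and other count-based tests were not run. Depth limits genes such as Mir7224, called on 3 reads per KO library.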

Other observations

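The gene groups and the tests of explanations in this part were chosen after the results were seen. Of 15 genes of MHC class I presentation 1 fell and 0 rose: Tapbp, which loads peptides on class I molecules, fell by 0.54 (adjusted p = 0.0497). Log2 changes were below 0 in 14 of the 15 (median −0.27), 11 had both KO libraries below both WT libraries, and the group as a whole was not tested. H2-D1 was at 1527 ± 2.54 and 1064 ± 99.9 FPKM (SD, n = 2, adjusted p = 0.139) and B2m at 2148 ± 83.8 and 2097 ± 56.2 (adjusted p = 0.911). The stefin and cystatin genes rose in 6 of 6 cases (median 1.38), with the limit that these copies share reads. Of 7 retinoid genes, Cyp26a1 and the carrier Rbp4 rose, the latter from 26.1 ± 2.23 to 61.5 ± 1.54 FPKM, while the median was 0.00403 (−0.041 to 0.049 with 1 library left out).

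Of 6 late erythroid genes (the globins, Alas2 and Fech) 5 rose, with a median of 2.24. The 5 early erythroid genes tested (Car1, Car2, Klf1, Gata1 and Rhd) all lay below WT in both KO libraries (median −0.72), and none of them passed the limma test. Their WT libraries lay far apart, as for Car1 at 9.39 ± 6.38 and 0.480 ± 0.186 FPKM, and the median was −0.36 without WT replicate 1 and −1.09 without WT replicate 2. Of 5 eosinophil genes 2 rose (median 0.50), and of 5 basophil and mast cell genes 2 fell (median −0.81), while the basophil protease Mcpt8 was at 37.2 ± 1.65 and 43.5 ± 1.84 FPKM (adjusted p = 0.217). Differences between these groups were not tested.

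The first pattern is higher mature neutrophil and lower macrophage, B, T and NK cell lists. A lower share of leukaemic cells in KO would raise the genes of all other cell types alike. The 35 macrophage, B, T and NK genes had a median log2 change of −0.47. Their lists define the pattern, so this median was known and is no separate test. It says only that such a lower share would not by itself give these falls. The median of globins and Alas2 was 2.36, a gap of 2.84. These were the erythroid genes already called higher, so that choice set the gap, which decides nothing. The whole erythroid list had a median of 0.37 and the early erythroid genes −0.72. A lower share of leukaemic cells in WT stays open. With neutrophils mixed in as the whole cause of the neutrophil rise, all tested members were predicted to rise. Of the 14 tested members under 50 FPKM in WT, 4 rose. Upper 95% limits lay below 0.65, the smallest called rise, for 5 (Fcnb, Mmp8, Csf3r, Cxcr2 and Ltf, the last with KO libraries far apart). The level of each member in neutrophils and in leukaemic cells was not measured, so its gain from such mixing is unknown and this cause stays open. Fewer macrophages in KO may account for the macrophage part: over 6 macrophage genes too low to be tested, summed reads were 289 and 375 in WT and 141 and 202 in KO, a ratio of 0.510 after scaling to depth. Reads of Cd163, Mrc1 and Msr1 carry that sum, while those of Mertk, Trem2 and Arg1 overlapped between the groups and the abundant Apoe was at 214 and 209 FPKM, so this stays open, as does an effect of genotype on differentiation, which was not tested.

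The second pattern is the higher level of small RNAs without poly(A) tails, with a median of 0.27 over 239 small RNA and rRNA genes (0.15 without WT replicate 1 to 0.33 without KO replicate 1). A difference in depth is argued against, because the assigned reads of the groups overlapped (0 on a scale where 1 means separated). More RNA without poly(A) tails carried through the selection would also raise another class that lacks them, the 17 histone genes. Their median of 0.44 lay at percentile 100 of 10000 protein-coding lists matched on level (median −0.010). The histone list had already been called higher, so this place was known and is no separate test. Histone genes also move together and KO replicate 2 stood apart, so this source stays open. More unspliced or genomic reads in KO stays open as well, since the median of 512 intronic, antisense and unreviewed gene models, 0.17, also lay at percentile 100 of such lists (median 0.07; 0.12 to 0.22 with 1 library left out). Many small RNA genes sit in introns, so these sources overlap, and an effect of genotype was not tested.

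The third pattern is that Rreb1 was not lower in KO. After an exchange of 1 WT with 1 KO library, the true groups would be 1 of the other divisions of the 4 libraries into pairs. The better of these called 0 genes, where the labelled one called 119. In the other divisions the difference between the labelled groups counts as spread, so few calls are likely there. Whether genotype is the largest difference between the libraries is not known here, so an exchange stays open. With 3 divisions in all, these counts do not bear on chance. A deletion that leaves most exonic reads cannot be told apart from an unchanged gene, since the KO to WT ratio of mean FPKM was 1.10 and only the sum over all exons was analysed here. An exchange of both pairs of labels would turn that ratio to 0.906 with all 4 libraries at 5.24 to 6.93 FPKM, so no assignment of the labels gives a group that has lost the transcript.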
